A study of Mus musculus with 12 samples.

How the data were processed

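Chromatin immunoprecipitation followed by sequencing was carried out on back skin of mice aged 8 to 10 weeks that received 5 Gy of ionizing radiation, per the labels' protocols. The antibodies were against p53, the transcription factor activated by DNA damage, and against trimethylated lysine 4 of histone H3 (H3K4me3), a mark of active promoters. The labels give 12 samples in 6 groups of 2: H3K4me3 in wild-type (WT) skin at T0 and at 6 h, p53 in WT skin at T0 and at 6 h, and p53 in K17KO skin at T0 and at 6 h. K17KO is the genotype as the labels write it, and its full name is not given in the sources used here. Whether the paired samples of a group came from separate animals is not given in the sources used here.

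The data analysed were 3 peak lists, for WT p53, K17KO p53 and H3K4me3. Only the K17KO list names a genotype, so WT was inferred for the other p53 list, which names its antibody alone. Every comparison of WT with K17KO below rests on this. No list names a library, time point, replicate or control, so each was treated as a single list of its antibody and genotype. The comparison of T0 with 6 h could therefore not be made, and no list has a replicate error. The tools were Bowtie2 version 2.2.5, SAMtools version 1.7 and MACS2 version 2.1.2, with mm10 as the genome build, per the submitters' processing notes, which give no role or order. The libraries and time points behind each list, the control and the call threshold are not given in the sources used here.

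Each list has 10 columns and no header. The deposited fold enrichment of a peak is a ratio of its fragment pileup to the caller's background. The deposited −log10 p and −log10 q are the caller's own values for that peak. The deposited score equals 10 times the −log10 p without its decimals in every peak. These values were used only to describe, rank or filter peaks within a list. The smallest −log10 q was 0.376 for WT p53, 1.04 for K17KO p53 and 0.229 for H3K4me3, so the lists were not cut at a common level.

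The depth behind each peak was recovered from the deposited fold and −log10 p. The fold was taken as the fragments at the summit plus 1 over the background plus 1, and p as the upper Poisson tail. A whole number of fragments reproduced both values within 0.001 in −log10 p for 100.0% of peaks in each of the 3 lists. With the p-values shuffled among peaks this share was 3.92% for WT p53, 2.00% for K17KO p53 and 5.20% for H3K4me3.

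Gene positions came from a RefSeq table of the mouse assembly GRCm38.p6, which shares its coordinates with mm10. It holds 49943 genes on chromosomes 1 to 19, X and Y, of which 21887 are protein-coding. The table gives no strand and no exons. The planned distance to a start site was therefore replaced by the distance to the nearer of the gene's ends, and exons, introns and untranslated regions were not told apart. This departs from the design fixed before the data were examined. The planned search for p53 motifs needs a genome sequence and was not run.

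Peaks counted as shared when they overlapped by at least 1 bp. The number shared by the p53 lists was set against 1000 random placements of the K17KO peaks on their own chromosomes (one-sided), and overlaps with H3K4me3 against 200 placements. Placement was uniform along each chromosome and kept no preference for gene ends. Lists that favour the same kinds of region can therefore exceed it without sharing specific sites. Random gene-end shares were averaged over 20 random copies of each list. Shares were compared with Fisher's exact test (two-sided) and have exact Clopper-Pearson intervals at 95%. The units are peaks or genes, so p-values and intervals cover counting only, not the spread between animals. Medians of shared and unshared peaks were compared with a two-sided permutation test of 100000 resamples.

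A gene had a peak when a peak midpoint lay within 5 kb of either gene end. Such a peak could lie inside a neighbouring gene or count for several genes, so tests over genes treat linked genes as independent. Before the data were examined, 19 gene lists were fixed with 510 members, of which 3 (Krt85, Mx1 and Trdc) matched no protein-coding gene. Each list was tested against all other protein-coding genes with Fisher's exact test and Benjamini-Hochberg adjustment over the 19 lists of a peak list, at 0.05. The named peaks are the 10 of highest fold in each list, the 10 of highest fold in only 1 p53 list, those in both, and up to 4 members of each gene list per peak list. Sites outside the gene lists are named by the nearest protein-coding gene, so noncoding genes are not named. Cdkn1a, Mdm2, Ccng1, Bbc3, Bax, Trp53inp1, Trp53, Krt17, Actb and Gapdh were always reported. Other genes are said to be chosen after their values were seen. Some members of the gene lists are counted but not reported by name here.

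The methods were tested on simulated data. All 200 planted overlaps were recovered among 2909 peaks, and all 200 planted genes among 21887. In the second test 271 genes were assigned a peak, because a peak counts for every gene with an end within 5 kb. Of 500 random lists of 40 genes, 15 had a Fisher p under 0.05. The alternatives covered the overlap rule, the peak threshold, the chromosomes, the list length, the distance to a gene and the peak value. Further alternatives were chosen after seeing the data: a common q-value, a background of at most 5 fragments, and peaks anywhere inside a gene, without allowance for gene length. For H3K4me3 folds at p53 target genes these were 10000 permutations matched on the number of peaks per gene, and the peak nearest a gene end. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.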

Results

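The series profiled p53 binding and H3K4me3 in mouse back skin at T0 and at 6 h under a 5 Gy radiation protocol, with p53 measured in WT and K17KO animals. The peak lists do not separate these times. The WT p53 list held 2909 peaks, the K17KO p53 list 1101 and the H3K4me3 list 5464. The median peak rested on 7 fragments over a background of 0.992 in the WT p53 list, on 11 over 1.39 in the K17KO p53 list, and on 148 over 90.7 in the H3K4me3 list. The median fold enrichment, as the authors deposited it, was 4.02, 4.60 and 1.66. At a q-value of at most 0.1 the lists kept 1754, 1101 and 4901 peaks. No list names its libraries, so no value below has a replicate error.

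Which genes p53 occupied in WT skin was examined first. Peaks lay at canonical p53 target genes, led by Bax, a mitochondrial apoptosis effector, at 6.70-fold, and Cdkn1a, the cyclin-dependent kinase inhibitor p21, at 6.57-fold. Phlda3, a repressor of Akt signalling, followed at 6.49-fold and Bbc3, which encodes the apoptosis activator Puma, at 6.03-fold. Lower folds were found at Rps27l (4.51), at Ccng1, which encodes cyclin G1 (4.40), and at Trp53inp1, a stress-induced p53 cofactor (4.02). The Cdkn1a peak spanned chromosome 17 from 29090757 to 29091094 (mm10), with its midpoint 54 bp outside the gene, and rested on 15 fragments over a background of 1.44. The Bax peak, on chromosome 7 from 45466448 to 45466762, lay inside the gene, 298 bp from its end, with 19 fragments over 1.98.

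In all, 10 of 56 p53 target genes had a WT p53 peak (17.9%, 95% interval 8.91 to 30.4), against 2.68% of other protein-coding genes (odds ratio 7.88, Fisher's exact p = 2.396e-06, adjusted p = 4.552e-05). Plk2 (4.72-fold), Steap3 (4.20) and Ephx1 (3.62) complete the 10 and are named after their values were seen. Mdm2, the ubiquitin ligase that degrades p53, had no WT p53 peak within 5 kb, and its nearest lay 73.5 kb away. No other list passed the adjusted test. Among dermal fibroblast genes 3 of 20 had a peak, namely Col3a1 (5.02-fold), Thy1 (4.03) and Col6a1 (3.06), with an adjusted p of 0.154. Single members of the H3K4 methylation machinery (Ash2l, 3.86-fold) and of the genes of other organs (Cpa1, 4.16) had a peak, and the remaining lists had none. When a peak anywhere inside a gene was counted, the p53 target call was lost (odds ratio 3.02, Fisher's exact adjusted p = 0.0742), and the other settings kept it with odds ratios from 3.28 (20 kb window) to 30.1 (q-value of at most 0.01).

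The WT peaks of highest fold were not at these protein-coding genes. Noncoding genes near those peaks were not considered, so whether any lay at a noncoding p53 target gene is not known. The highest, at 10.18-fold with 31 fragments over 2.14, lay on chromosome 4 from 150048925 to 150049353, outside protein-coding genes and 38364 bp from Gpr157. It was followed by peaks 172006 bp from Zc3h15 (9.54-fold) and 357588 bp from Zwint (9.44-fold), and by peaks near Pkd2l1 (8.54-fold) and inside Tmem43 (7.88-fold). The other 5 of the top 10 lay nearest Gm21885, Ereg, Prlr, Arhgap29 and Kcnq5, at 7.35-fold to 7.73-fold. Ereg encodes the growth factor epiregulin, and its peak lay 16528 bp outside the gene.

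**Figure D1:**
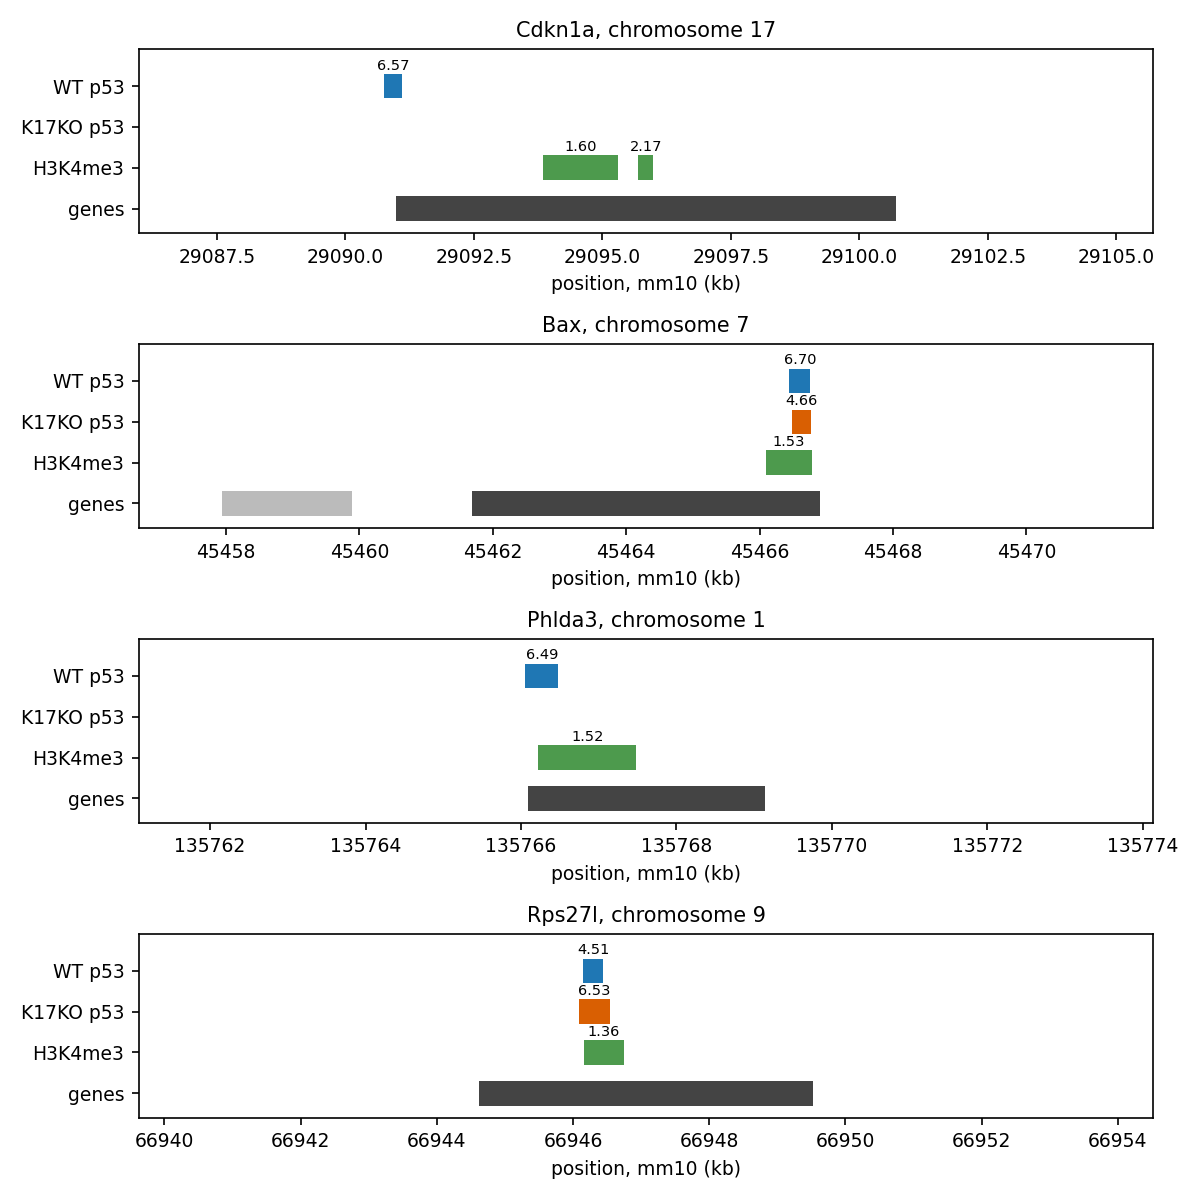
Peaks of the 3 lists around 4 p53 target genes, with mm10 position in kb on the horizontal axis, the named gene in dark grey, the neighbouring gene Ftl1 in light grey and the deposited fold enrichment above each peak. WT p53 peaks lie at all 4 genes, K17KO p53 peaks at Bax (4.66-fold) and Rps27l (6.53-fold), and H3K4me3 peaks at all 4.

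The K17KO p53 list answered the same question for the second genotype. Of the p53 target genes, Rps27l (6.53-fold, 18 fragments over 1.91) and Bax (4.66-fold, 17 over 2.87) had a K17KO peak. Cdkn1a, Bbc3, Ccng1, Trp53inp1 and Mdm2 had none within 5 kb. The nearest K17KO peak to Cdkn1a lay 59.3 kb away and the nearest to Ccng1 14.5 kb away. The count of 2 of 56 (3.57%, 95% interval 0.435 to 12.3) did not differ from that of other genes at 2.37% beyond counting error (odds ratio 1.53, Fisher's exact p = 0.385, adjusted p = 1). No gene list passed in any setting. The p53 target odds ratio ran from 0.940 with peaks anywhere inside a gene to 3.097 in the upper 50% of the list by fold, with 1.82 at 20 kb (5 of 56) and 2.05 at a q-value of at most 0.01, and the Fisher's exact adjusted p was 1 in each. Members with a peak included Bard1, the partner of Brca1 (6.65-fold), Fancd2 of the Fanconi anaemia pathway (4.09), Hoxc13, a hair shaft regulator (4.87), and the Notch effector Rbpj (4.63). Mki67 (3.73), Men1 (3.62) and Gfap (4.32) also had a peak.

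Among the 10 K17KO peaks of highest fold, Epm2a, which encodes the glycogen phosphatase laforin, led at 8.52-fold with its peak inside the gene, 1181 bp from an end. Bicd1 and Hsp90b1, an endoplasmic reticulum chaperone, each had a 7.67-fold peak, 231 and 407 bp from an end, and both overlapped an H3K4me3 peak. Tnpo3, Dnajc10, Snx25 and Etv3 had peaks of 7.20-fold inside the gene. The other members of the top 10 lay nearest Cypt14, Olfr765 and Atg10, all outside protein-coding genes.

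The direct comparison of genotypes found 9 peaks in both p53 lists. They lay at Bax (6.70-fold in WT, 4.66-fold in K17KO), Rps19, a ribosomal protein gene (6.44 and 4.91), Rps27l (4.51 and 6.53), Cdc34, a ubiquitin-conjugating enzyme gene (3.87 and 4.58), and Ndnf (3.38 and 4.12). The others were the site nearest Gpr157 (10.18 and 6.98) and sites nearest Pparg (3.38 and 4.41), Gm45871 (3.0 and 3.13) and Smgc (2.98 and 2.26). The Gm45871 site, on chromosome 18 from 90602249 to 90602545, had a WT background of 50.6 fragments, and the Smgc site a K17KO background of 28.7. The WT peaks at Ndnf and nearest Pparg each rested on 6 fragments over 1.07, with a −log10 q of 0.66. Folds of separate lists are given side by side and were not compared.

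The 9 peaks made up 0.309% of the WT list (95% interval 0.142 to 0.587) and 0.817% of the K17KO list (0.374 to 1.55). Random placement gave a mean of 0.930 and a maximum of 6, and the permutation p of 0.001 is the smallest that 1000 placements can give. This placement ignored gene ends, which both lists favour, so the excess may partly reflect a common preference for such regions. The count was 4 among the upper 50% of each list by fold, 4 with the WT list limited to 1101 peaks, 7 at a q-value of at most 0.1 and 5 at 0.01. Within the WT list, shared and unshared peaks had median folds of 3.87 and 4.02 (permutation p = 0.656), and within the K17KO list 4.58 and 4.60 (p = 0.892). By −log10 p the shared peaks ranked higher, with medians of 8.77 against 5.01 in WT (permutation p = 1e-05, the smallest possible) and 9.13 against 6.91 in K17KO (p = 0.00508).

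At the level of genes, 596 had a WT peak, 519 a K17KO peak and 26 both, against 14.1 expected for independent lists (odds ratio 1.92, Fisher's exact one-sided p = 0.00227). A single shared site can count for several neighbouring genes, so the p-values of this gene overlap may be too small. With a window of 1 kb there were 5 such genes (odds ratio 2.38, Fisher's exact p = 0.0665), and with the upper 50% of each list 6 (1.92, p = 0.102). The other settings kept the call, with 119 genes at 20 kb (odds ratio 1.304, Fisher's exact p = 0.00567), 110 inside genes (2.201, p = 5.846e-12), 15 at a q-value of at most 0.1 (1.964, p = 0.0141) and 6 at 0.01 (4.80, p = 0.00233). Of the p53 target genes, 8 were among the 570 with a WT peak only and 0 among the 493 with a K17KO peak only. This difference had a Fisher's exact p of 0.00876 and an adjusted p of 0.166 over 19 lists, so it did not pass. No other list differed, with the dermal fibroblast genes at 3 and 0 (Fisher's exact adjusted p = 1).

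The position of p53 peaks relative to genes differed between the lists. Midpoints within 1 kb of a gene end made up 28.1% of K17KO peaks (95% interval 25.4 to 30.8) and 10.5% of WT peaks (9.39 to 11.7), with 65.1% of H3K4me3 peaks as a reference. Random placement gave 6.42%, 6.20% and 6.35%. The K17KO share was 17.6 percentage points higher (odds ratio 3.33, Fisher's exact p = 1.858e-39). For protein-coding genes alone the shares were 22.0% and 5.50%. Peaks over 50 kb from any protein-coding gene end made up 26.3% of the K17KO list and 39.0% of the WT list (Fisher's exact p = 3.982e-14). Both genotypes are a single list each, so genotype and list cannot be separated. Peak widths differed too, with medians of 216 bp in WT and 335 bp in K17KO and minima of 216 and 291 bp.

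**Figure D2:**
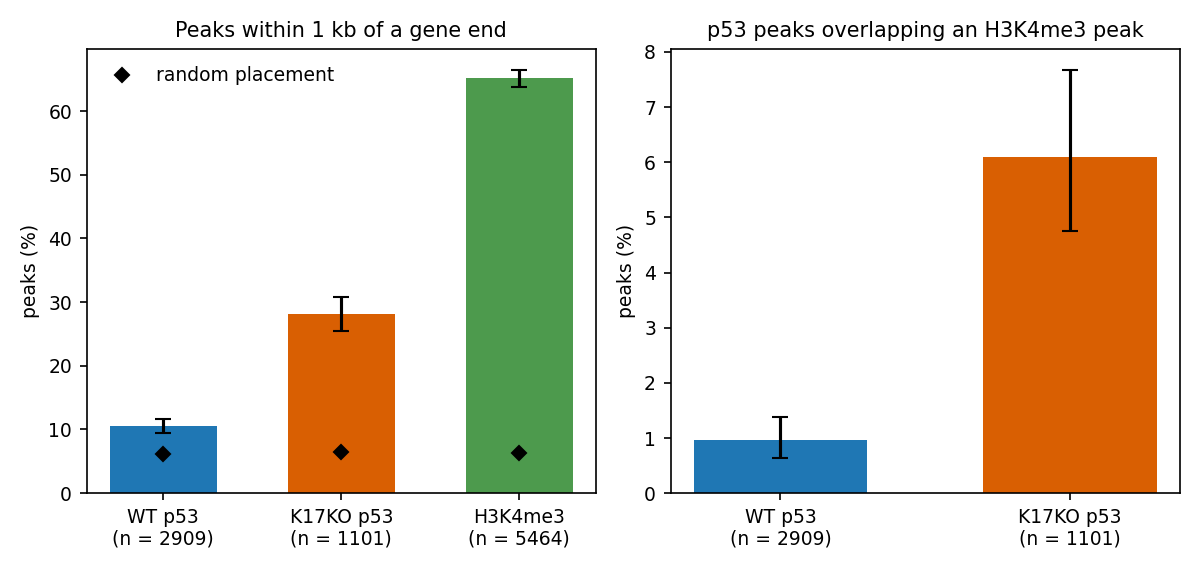
Left, the percentage of peaks with a midpoint within 1 kb of a gene end in each list, and right, the percentage of p53 peaks overlapping an H3K4me3 peak. Bars are shares, error bars exact 95% binomial intervals and diamonds random placement; K17KO p53 exceeds WT p53 in both panels (28.1% against 10.5%, and 6.09% against 0.963%).

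Overlap of p53 peaks with H3K4me3 was measured next. In the WT list 28 peaks overlapped an H3K4me3 peak (0.963%, 95% interval 0.641 to 1.39), among them those at Bax, Phlda3, Rps27l, Ccng1, Trp53inp1, Ephx1 and Rps19. In the K17KO list 67 did (6.09%, 4.75 to 7.66), among them those at Bicd1, Hsp90b1, Bax, Rps27l and Rps19. Random placement, which ignored gene ends, gave means of 3.89 and 1.81 peaks. The K17KO share was 5.12 percentage points higher (odds ratio 6.67, Fisher's exact p = 1.157e-18). Among peaks within 1 kb of a gene end it was 16.8% against 6.56% (Fisher's exact p = 8.313e-05), and among other peaks 1.89% against 0.307% (p = 2.1e-05). In the upper 50% of each list by fold the difference was 1.34 points (Fisher's exact p = 0.0104). The H3K4me3 libraries were from WT skin only, and the control behind that list is not given in the sources used here. If that control itself carried H3K4me3, a peak in the list marks a difference from it rather than presence of the mark. In all, 4 sites were in all 3 lists, at Bax, Rps19, Rps27l and the site nearest Gpr157.

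The H3K4me3 list was described by the genes it covered, since it names no time point. A peak in it may mark a difference from its control rather than presence of H3K4me3. Peaks lay within 5 kb of an end of 35 of 56 p53 target genes (62.5%, 95% interval 48.5 to 75.1), against 21.4% of other genes (odds ratio 6.13, Fisher's exact adjusted p = 7.408e-10). Tigar, Xpc and Polh, named after their values were seen, had their highest-fold peaks inside the neighbouring genes Fgf23, Lsm3 and Xpo5. The highest folds were at Ephx1, an epoxide hydrolase gene (4.78), Mdm2 (3.40), Eda2r (3.10) and the death receptor gene Fas (2.82). Cdkn1a (2.17), Bbc3 (2.03), Bax (1.53) and Ccng1 (1.49) had lower folds, and Trp53inp1 had 2.25. The Mdm2 peak spanned chromosome 10 from 117708914 to 117709235, inside the gene and 1684 bp from its end, with 61 fragments over 17.2. Trp53 had a peak 453 bp from its end (1.37-fold).

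Cell cycle genes had peaks at 22 of 40 members (55.0%, odds ratio 4.48, Fisher's exact adjusted p = 3.463e-05), led by the mitotic kinase gene Aurka (2.1-fold), the cyclin genes Ccnb2 (1.94) and Ccne2 (1.92), and Myc (1.91). The H3K4 methylation machinery had 11 of 19 (odds ratio 5.04, Fisher's exact adjusted p = 0.00375), among them Setd1b (1.72) and Men1 (1.66), but not with a 1 kb window (adjusted p = 0.148) or in the upper 50% by fold (adjusted p = 0.910). The Setd1b and Men1 peaks lay inside the neighbouring genes Rhof and Map4k2. Apoptosis regulators had 12 of 28, led by Birc3 (2.83), Hrk (2.62) and Bad (1.85), at an adjusted p of 0.0480. That call was lost with every other window and threshold tried (adjusted p from 0.0805 to 0.910).

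The other lists did not pass at the 5 kb window with all peaks. Hair follicle stem cell genes had 9 of 20, including Runx1 (4.09-fold), Hopx (3.77) and Id2 (2.18), with an adjusted p of 0.0893. They passed at a q-value of at most 0.1 (Fisher's exact adjusted p = 0.0345) or 0.01 (0.0126) and with peaks inside genes (0.0126). DNA damage signalling and repair had 12 of 42, with Xrcc1 (2.05) highest, inflammation and interferon 11 of 40, with Ifit1 (3.94) and Ifit3 (3.14), and Wnt, Hedgehog, Bmp and Notch signalling 11 of 35. Epidermal differentiation had 8 of 35, among them the keratin genes Krt1 (4.84) and Krt10 (4.28), the basal keratinocyte list 4 of 20, with Krt15 (2.69), and the hair shaft and inner root sheath list 5 of 36. Krt17 had no peak in any list within 5 kb, its nearest H3K4me3 peak being 59.1 kb away. Markers of other cell types with a peak were 1 of 20 dermal fibroblast, 2 of 15 endothelial, 1 of 19 immune, 1 of 11 melanocyte, 2 of 14 adipocyte and 1 of 15 skeletal muscle genes. The peaks counted for Xrcc1, the immune gene Cd3g and the muscle gene Actn3 lay inside the neighbouring genes Pinlyp, Ube4a and Zdhhc24. The dermal fibroblast share was below that of other genes with a 20 kb window (odds ratio 0.113, Fisher's exact adjusted p = 0.0273). Genes of other organs had 1 of 25 (Fisher's exact adjusted p = 0.0893), and 0 at a q-value of at most 0.1 (adjusted p = 0.0345).

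Ubiquitously active genes, whose promoters carry H3K4me3 in most tissues, had a peak at 4 of 20 (20%, 95% interval 5.73 to 43.7), among them Hsp90ab1 (1.60-fold), Eif4a2 (1.51) and B2m (1.35). Other protein-coding genes had 21.5%. With a 20 kb window the count was 13 of 20 (65%) against 31.8% of other genes, and the list passed (odds ratio 3.99, Fisher's exact adjusted p = 0.0177). Actb and Gapdh, which encode a cytoskeletal actin and a glycolytic enzyme, had no peak within 5 kb, and the nearest lay 8.10 kb and 49.4 kb away. Genes with a p53 peak overlapped those with an H3K4me3 peak in both genotypes, with 161 of 596 in WT (128 expected, Fisher's exact one-sided p = 0.000678) and 166 of 519 in K17KO (111.5 expected, p = 1.205e-08). The H3K4me3 peaks of highest fold lay mostly far from gene ends, led by a 10.28-fold peak inside Hdac4, 68196 bp from its end. A peak nearest Samd9l had 202 fragments over a background of 22.4. Pink1, a mitochondrial kinase gene, had a 7.33-fold peak 1495 bp from its end, and a 6.82-fold peak lay inside Ptch1, the Hedgehog receptor gene. The others of the top 10 lay nearest Nfam1, Rps12, Gbp5, Arhgef12, Pdlim5 and Camk1d.

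**Figure D3:**
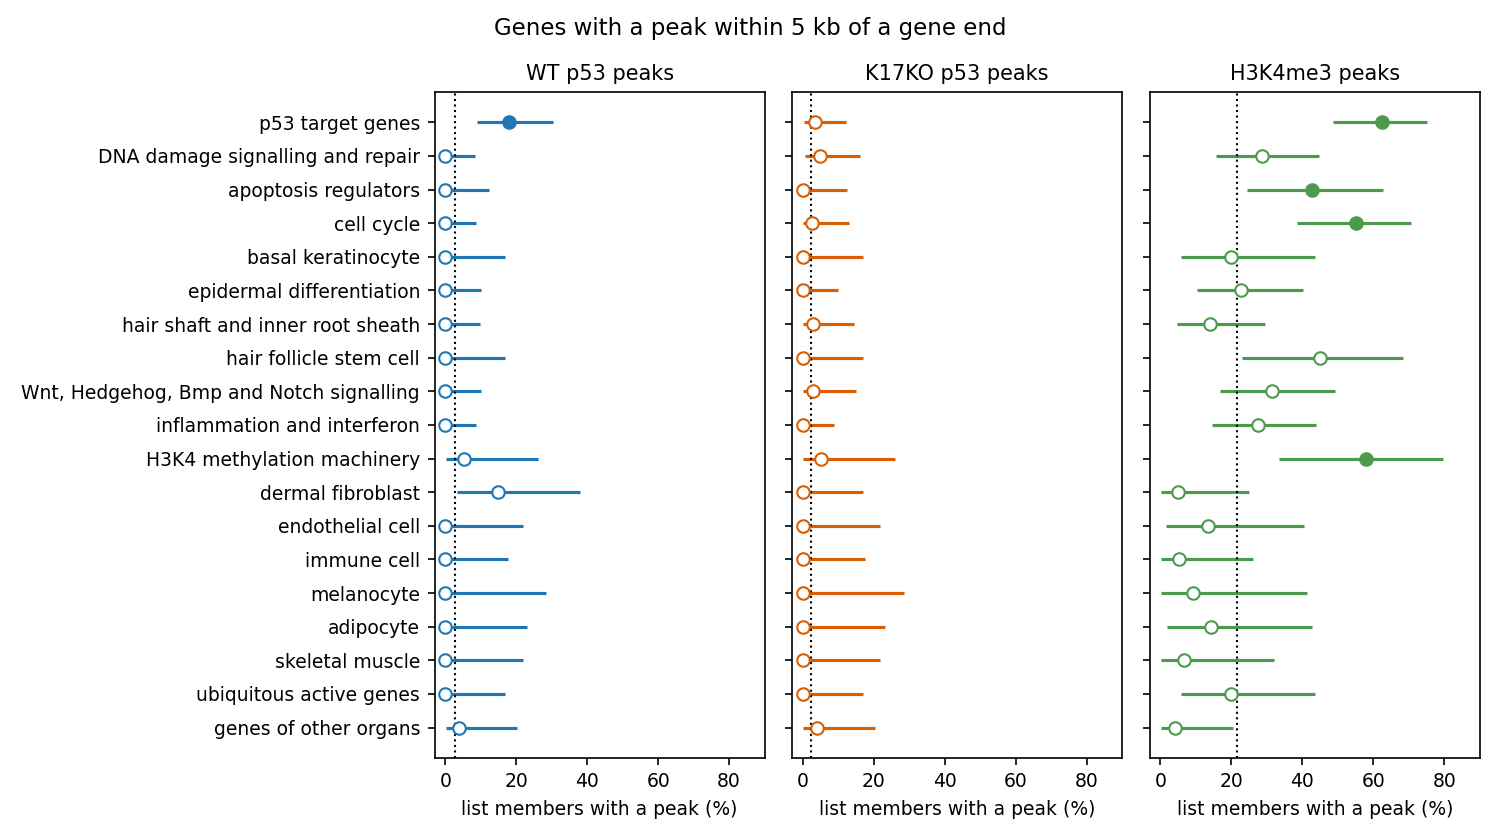
Percentage of the members of each of 19 gene lists with a peak within 5 kb of a gene end (horizontal axis), by peak list. Lines are exact 95% intervals, filled points lists with an adjusted p under 0.05 and dotted lines the share of other genes; p53 target genes stand at 17.9% for WT p53, 3.57% for K17KO p53 and 62.5% for H3K4me3.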

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

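All tests of explanations given here were chosen after the results were seen. The p53 peaks of the K17KO list differed from those of the WT list in their share within 1 kb of a gene end (17.6 percentage points higher), by a test of the difference itself. Different call thresholds were examined with both lists held to a q-value of at most 0.1, where the difference was 18.1 points (95% interval 15.1 to 21.1). All 1101 K17KO peaks already met that limit, so it removed WT peaks only. Each list's q-values come from its own call, so an equal q-value is not an equal threshold and unequal calling is not excluded. Weak WT peaks away from genes would have to remove the difference at a q-value of at most 0.01, where it was 18.4 points (13.9 to 22.9). Signal at active gene ends unrelated to p53 cannot be told apart from binding, because only 2 p53 target genes had a K17KO peak within 5 kb (odds ratio 1.53, interval 0.180 to 5.82). Genotype, the biological explanation in the design, was untested and remains open with any difference between the libraries, since each genotype is a single list that names no library or time point.

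The p53 lists shared 9 peaks. Had noise among weak WT peaks been the whole reason, and had the K17KO list recovered true sites, most of the strongest WT peaks should have been shared. Of the 27 WT peaks with a −log10 q of at least 5 and a background of at most 5 fragments, 3 were (11.1%, 95% interval 2.35 to 29.2). The K17KO list held a peak at only 2 of 56 p53 target genes, so its recovery of true sites is not established. The low share therefore does not rule out noise. Lower recovery of the same sites in K17KO cannot be told apart from a difference in sites: WT peaks kept in K17KO did not have a higher fold than the others (difference of medians −0.143, permutation p = 0.656), while their −log10 p was higher by 3.76. Of the p53 target genes, Bax with the highest WT fold (6.70) and Rps27l (4.51) had a peak in the K17KO list, while Cdkn1a (6.57), Phlda3 (6.49) and Bbc3 (6.03), with WT folds between them, had none. Genotype was untested.

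The share of p53 peaks overlapping an H3K4me3 peak also differed by a test of the difference itself, with K17KO 5.12 percentage points higher, 3.84 at a q-value of at most 0.01 and 1.34 in the upper 50% of each list by fold, and it counts overlap with a list whose control is not given.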

How the results depend on the processing

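The common q-value, the limit on background and the count of peaks inside genes were chosen after seeing the data. Over 19 results, 83 of 115 alternative values kept their direction and side of the threshold or, for counts of shared peaks and of called lists, stayed within 1.5 times the main count, among them all for the genotype differences in gene-end share (13.7 to 18.8 points) and H3K4me3 overlap (1.34 to 5.22 points). The shared p53 peaks numbered 4 in the upper 50% by fold, 4 with the WT list at 1101 peaks and 5 at a q-value of at most 0.01, where fewer peaks enter, each with a permutation p of 0.001. The median folds of shared and other p53 peaks did not differ past the threshold, while shared peaks were higher by −log10 p (3.76 in WT, 2.23 in K17KO), −log10 q (2.42, 1.51) and width (80 and 75 bp). Odds ratios that lost their call were 2.38 (1 kb) and 1.92 (upper 50%) for genes shared by the p53 lists, 3.05 (1 kb) and 1.27 (upper 50%) for H3K4 methylation machinery, and for apoptosis regulators 2.48 (1 kb), 1.86 (20 kb), 1.29 (upper 50%), 2.26 (q 0.1), 2.40 (q 0.01) and 2.39 (inside genes). Counting peaks inside genes gave p53 target odds ratios of 3.02 in WT and 0.940 in K17KO, and 0 called lists in WT. In the other settings the K17KO odds ratio ran from 1.45 (1 kb) to 3.097 (upper 50%), without a call. H3K4me3 had 2 called lists with 1 kb and 2 in the upper 50%, 5 with 20 kb and 5 at q 0.1, and 4 otherwise. Odds ratios that gained a call were 3.33 (q 0.1), 4.14 (q 0.01) and 3.903 (inside genes) for hair follicle stem cell genes, 0.113 (20 kb) for dermal fibroblast genes and 0.0797 (q 0.1) for genes of other organs. The odds ratio of ubiquitously active genes turned from below to above 1, at 1.31 (1 kb) and 1.02 (q 0.1) without a call and 3.99 (20 kb) with one. Where no reason is given, the cause was not tested. Motif and time alternatives were not run, and no replicate could be left out. No paired analysis was possible because the lists name no samples. Depth limits the p53 lists, whose median peaks rest on 7 and 11 fragments.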

Other observations

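All tests in this part were chosen after the data were seen, and the gene lists in it were written then. Genes of the circadian clock had H3K4me3 peaks at 16 of 22 members (72.7%), against 21.4% of other genes (odds ratio 9.78, Fisher's exact adjusted p = 3.91e-07). They included Per1 (2.71-fold), Per2 (2.66), Cry2 (2.59) and Dbp (2.46). Genes known to respond to glucocorticoids had peaks at 15 of 17 (odds ratio 27.5, Fisher's exact adjusted p = 1.636e-08), among them Zbtb16 (3.04-fold), Pdk4 (2.60), Klf9 (2.5) and Tsc22d3 (2.29), with Per1 in both lists. Some members were in mind as H3K4me3 genes when the lists were written, among them Per2 in the clock list and Zbtb16, Tsc22d3 and Fkbp5 in the other. Without all such members the counts were 14 of 20 (odds ratio 8.55, Fisher's exact adjusted p = 4.462e-06) and 12 of 14 (odds ratio 22.0, adjusted p = 1.113e-06). Adjustment covered only these added lists. Leaving out these members does not make the remaining ones independent of the data, so the p-values are descriptive. The list names no time point, so whether these peaks differed between T0 and 6 h could not be examined.

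The H3K4me3 list covered 35 of 56 p53 target genes but 4 of 20 ubiquitously active genes at 5 kb (Fisher's exact p = 0.00152), a contrast that did not pass at 1 kb (26 and 4, p = 0.0607) or 20 kb (40 and 13, p = 0.584). Peaks called without a control library are argued against by the backgrounds, of which 87.0% were whole multiples of a single step of 0.935 fragments, within 0.005 steps, against at most 2.07% after random shifts. A control without enrichment at gene ends is argued against by the median background at gene-end peaks, 89.2 times the lowest of the list (95% bootstrap interval 87.1 to 90.6), with 1.11 and 1.47 times in the WT and K17KO p53 lists. A control that itself carried H3K4me3, such as the other time point, may account for both values and for the 20% share of ubiquitously active genes at 5 kb. The list would then hold differences in H3K4me3 rather than its presence, and which time was higher was not tested.

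The highest H3K4me3 fold per gene had a median of 1.79 at 35 p53 target genes and 1.58 at 4667 other genes (difference 0.216, permutation p = 0.00245). The p53 target genes had a mean of 1.60 peaks per gene and the others 1.17. Permutations matched on that number gave a mean difference of 0.0865, and against them the observed one did not pass (permutation p = 0.0616). By the peak nearest a gene end the medians were 1.65 and 1.55 (permutation p = 0.0632), so a higher fold at p53 target genes cannot be told apart from their larger number of peaks. Of the 10 p53 target genes with a WT p53 peak 9 also had an H3K4me3 peak, against 26 of the other 46, a difference of 33.5 percentage points that did not pass (Fisher's exact p = 0.0719). Peaks per megabase were 8.63 times as frequent on autosomes as on chromosome X in the WT p53 list, 10.6 times in the K17KO p53 list and 3.86 times in the H3K4me3 list. Chromosome Y held 8, 4 and 1 peaks in these lists. The number of X copies in the animals was not taken into account, and the cause of the ratios was not tested.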
